A study of Mus musculus with 16 samples.

How the data were processed

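The data were the values deposited for 16 mouse tumours measured with the NanoString nCounter mouse PanCancer Immune panel, 1 column per tumour. The labels give the line (MC38 or E0771), the mouse number and the hypoxia status (hypoxic or normoxic), from which the 4 groups were formed. Per the labels, all mice received immunotherapy directed at PD-1 and CTLA-4, and tumours were taken after the imaging of day 5 and kept in RNAlater. Cartridges, run dates and RNA input are not given in the sources used here, so a batch that follows the line cannot be told apart from it.

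The table held 784 probes: 770 genes, 8 negative-control probes and 6 positive-control probes. The unit of the deposited values is a normalized signal on a linear scale, and the authors' processing steps and software are not given in the sources used here. The values themselves show the scaling. The geometric mean of the 20 housekeeping genes was 780 in every tumour, so each tumour had been multiplied by 1 factor set on those genes, and genes under 1 had been raised to 1. Control probes held whole numbers and had not been scaled, and background had not been subtracted. In every tumour 100% of gene values lay within 0.1 step of a whole multiple of 1 step, the tumour's scaling factor (0.631 to 3.52). Dividing by it gave estimated counts before scaling, which describe depth and serve in alternatives only; no count model was the main test. A factor set on housekeeping genes makes every difference relative to those genes. If their RNA is a larger share of the RNA of hypoxic tumours, all other genes appear lower there.

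The estimated gene counts per tumour ran from 180274 to 890239 (median 531770). A tumour with few counts has a large factor, which also multiplies its background: the mean of the negative probes times the factor ran from 2.69 to 24.6, with 24.6 in E0771 hypoxic 22, 17.4 in E0771 hypoxic 12 and 15.6 in E0771 normoxic 65. Genes near this level are measured with the least precision.

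The groups, comparisons, gene lists, named genes and most alternatives were fixed before the data were examined. Genes were tested when their mean over the tumours reached 24.0, the mean plus 2 SD of the negative probes. The negative probes were multiplied by each tumour's factor for this, a step decided once they were seen to be unscaled. This left 712 genes and excluded 58. Values entered as log2(value + 1), so differences of genes with low values are understated. The model in limma 3.58.1 (R 4.3.3; lmFit, then eBayes with trend) held the means of the 4 groups over all 16 tumours without further covariates. 5 contrasts were taken: hypoxic minus normoxic in each line, their mean, their difference, and E0771 minus MC38. Adjusted p-values are Benjamini-Hochberg values over the 712 genes, with a threshold of 0.05, and were also computed over each list alone. The median standard error of a difference was 0.57 in E0771, 0.55 in MC38 and 0.40 for the mean of both lines.

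25 lists of immune, stromal, tumour and hypoxia genes were tested with fry (two-sided), with camera at an estimated correlation, and by permuting tumours on the mean log2 level of a list, with Benjamini-Hochberg adjustment over the 25. They are T cell, CD8 and cytotoxic, NK cell, B cell, regulatory T cell, checkpoint, macrophage, immunosuppressive myeloid, neutrophil, dendritic cell, mast cell and eosinophil, MHC class I, MHC class II, type I interferon, interferon gamma and Th1, T cell attracting chemokine, myeloid attracting chemokine, inflammatory cytokine, NF-kB and Toll-like receptor, complement, endothelial, fibroblast, epithelial, apoptosis and hypoxia genes. The correlation of hypoxia effects between lines was tested over all 3920 relabellings of hypoxia status within line. Probe names were matched to mouse gene symbols of assembly GRCm38.p6, 756 by symbol and 8 by synonym, and 6 kept their name.

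Genes named in the text are, per comparison, up to 12 with the largest rise and up to 12 with the largest fall among those that passed, the 10 of smallest p where fewer than 10 passed, 24 measured genes of a list of 25 of general interest in each hypoxia comparison, and members at both ends of each gene list. Genes named outside this rule are said to be so where they appear.

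The alternatives were centring on each tumour's median gene or on the housekeeping genes, other filters (none, a mean of 50), a pseudocount of 10, eBayes without trend or with robust estimation, array quality weights, fits of 1 line only, an additive model, an adjusted p of 0.10, and leaving out each tumour. Added after seeing the data were background subtraction, precision weights from the estimated counts (voom), a filter at a mean of 20, leaving out the 3 E0771 tumours or all 5 tumours under 350000 estimated counts, scaling on the positive-control probes, and the mouse number as a random block between lines. The estimation of array quality weights stopped before it converged. Scaling on the positive-control probes does not correct for differences in RNA input between tumours.

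Simulated data took the means and spread of the 712 genes from tumours of both lines, with 50 genes changed per size in 20 runs. The model was tested on these data for the MC38 comparison. With independent noise it recovered 30.4%, 73.4%, 93.6% and 98.7% of genes changed by 1, 2, 3 and 4 on the log2 scale, with 3.55% of calls false, and with a factor shared by all genes of a tumour 27.7%, 75.4%, 93.8% and 99.0%, with 4.61% false. With that shared factor and no effect, 2 of 100 runs called any gene, up to 478 of them. With independent noise, a B cell list lowered by 2 on the log2 scale was called in 20 of 20 runs. The shared factor was left out of these runs, so they do not show how often a list is recovered when genes move together. Figures were drawn with matplotlib 3.10.9 from tables made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.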

Results

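RNA was measured in 16 mouse tumours with the NanoString mouse PanCancer Immune panel, in which colour-coded probes count the transcripts of a fixed set of immune and cancer genes without amplification. 8 tumours were grown from MC38, a mouse colorectal cancer cell line, and 8 from E0771, a mouse breast cancer cell line, each implanted at the shoulder. All mice had received immunotherapy directed at PD-1 and CTLA-4, receptors that restrain T cells, and the tumours were taken after imaging on day 5 after treatment. The labels class each tumour as hypoxic or normoxic. The study's design describes PET imaging with fluoromisonidazole, a tracer that is retained in cells low in oxygen; the uptake values were not analysed here. There were 4 hypoxic (mice 12, 14, 17 and 25) and 4 normoxic (mice 4, 7, 10 and 21) MC38 tumours. There were 3 hypoxic (mice 12, 22 and 55) and 5 normoxic (mice 4, 17, 38, 65 and 71) E0771 tumours. Within a line every tumour has its own mouse number, and tumours of untreated mice were not analysed here.

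Of 770 panel genes, 712 were tested. The estimated gene count of a tumour before the deposited scaling ran from 180274 in E0771 hypoxic 22 to 890239 in MC38 normoxic 4, with a median of 531770. The other tumours under 350000 were E0771 hypoxic 12 (192035), MC38 hypoxic 14 (274508), MC38 hypoxic 25 (312581) and E0771 normoxic 65 (315231). The first principal component of the log2 values held 58.1% of the variance, and 87.4% of the genes had loadings of one sign on it. MC38 normoxic 4, 7 and 21 lay at 26.7 to 43.5 on this component and MC38 hypoxic 12, 14 and 25 at -37.7 to -19.9. MC38 normoxic 10 (-4.46) and MC38 hypoxic 17 (-4.05) lay side by side between them. The second component (17.3%) separated the lines.

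**Figure D1:**
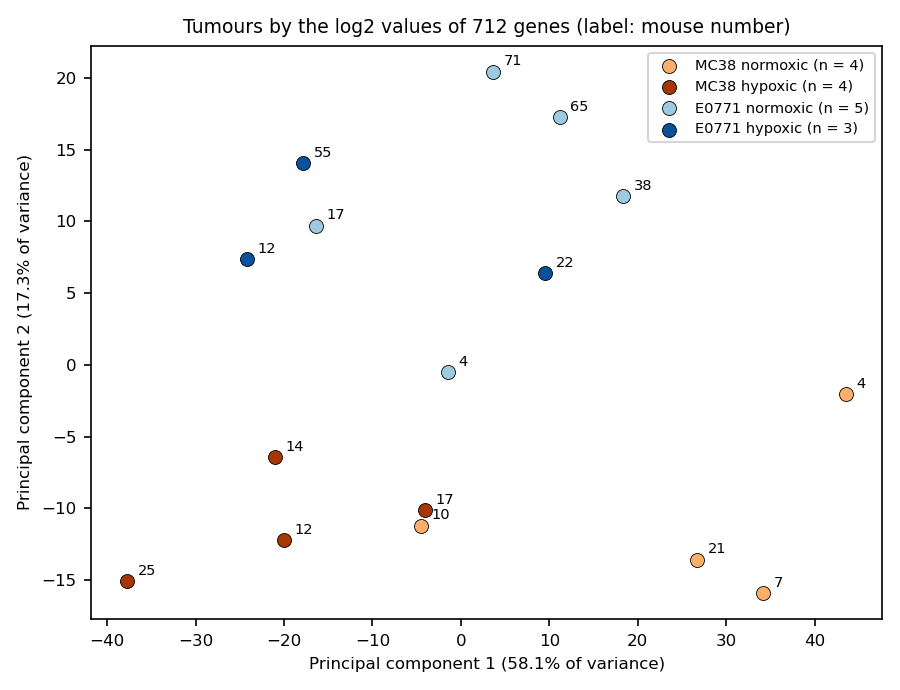
Scores of the 16 tumours on the first (58.1% of the variance) and second (17.3%) principal components of log2 values, 1 point per tumour, labelled by mouse number and coloured by line and hypoxia status. MC38 normoxic 10 (-4.46) and MC38 hypoxic 17 (-4.05) lie beside each other on the horizontal axis, and all E0771 tumours lie above all MC38 tumours on the vertical one.

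The first comparison asked which immune genes differ between hypoxic and normoxic MC38 tumours. Ccl24, a chemokine that draws eosinophils, fell by 5.53 ± 1.11 on the log2 scale (SE; 15.2 ± 8.73 normalized counts in hypoxic and 4977 ± 9459 in normoxic tumours, SD, n = 4 and 4). Chil3, a chitinase-like protein of alternatively activated macrophages, fell by 5.22 ± 1.04 (58.0 ± 32.0 against 11640 ± 21768). Arg1, the arginase that depletes arginine around T cells, fell by 4.04 ± 1.01 (667 ± 817 against 15760 ± 24987). The haemoglobin scavenger receptor gene Cd163 fell by 4.00 ± 0.99 (101 ± 93.0 against 3628 ± 6104). For each of these 4 genes all 4 hypoxic tumours lay below every normoxic tumour (adjusted p = 0.00732 for Ccl24 and Chil3 and 0.00812 for Arg1 and Cd163). Mouse 4 carried the normoxic means of all 4, with 19165 counts of Ccl24 (160 to 412 in the other normoxic MC38 tumours), 44286 of Chil3 (378 to 1258), 53233 of Arg1 (2734 to 3969) and 12771 of Cd163 (333 to 1032). Over the 16 fits without 1 tumour the log2 differences were -6.23 to -3.93, -6.0 to -3.71, -4.80 to -3.03 and -4.59 to -2.83, and each passed in every fit.

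In all, 346 of the 712 genes passed at an adjusted p under 0.05 in MC38 (limma), of which 342 were lower and 4 higher in hypoxic tumours. The median of all genes was -1.27, and 87.2% of genes had negative values. The other genes among the 12 largest falls were Cd209e (-4.12 ± 0.98), a C-type lectin, Prg2 (-3.85 ± 0.80), the major basic protein of eosinophils, and Pdcd1lg2 (-3.68 ± 0.75), which encodes the PD-1 ligand PD-L2. They further included Ccr3 (-3.65 ± 0.83), the eosinophil chemokine receptor, and Cxcr1 (-3.61 ± 0.81), a neutrophil chemokine receptor. Ifna1 (-3.60 ± 0.94), Il4 (-3.57 ± 0.78) and Il25 (-3.48 ± 0.86), which encode an interferon and cytokines of type 2 immunity, completed these. Of the 342 genes that fell, 129 had a hypoxic mean under the filter level of 24.0, among them Cxcr1 (6.08), Prg2 (8.56), Ccl24, Il4 (16.8), Il25 (20.7) and Cd209e (23.3), and many of the list members named below. In these tumours the scaled negative probes averaged 2.86 to 6.82, and the hypoxic means of 6 of the 342 lay under the highest of these. All 12 passed in each of the 16 fits without 1 tumour. The 8 of these fits without an E0771 tumour leave the MC38 differences as they are and change only the estimate of spread. The 4 genes that rose were Msln (1.65 ± 0.62; 478 ± 130 against 200 ± 183; adjusted p = 0.0361), which encodes the surface protein mesothelin, the interferon-induced genes Oasl1 (1.07 ± 0.42, adjusted p = 0.0430) and Ifi35 (1.0 ± 0.36, adjusted p = 0.0292), and C1qbp (0.98 ± 0.38, adjusted p = 0.0440), a mitochondrial protein that binds complement C1q. All 4 hypoxic tumours lay above the normoxic mean for each. None of the 4 passed without MC38 normoxic 4, normoxic 7, hypoxic 14 or hypoxic 25 (Msln 1.19 to 2.20 and Ifi35 0.66 to 1.32 over all 16 fits without 1 tumour).

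The number of MC38 calls depended on tumours and on scaling. It fell to 171 without hypoxic 25, 175 without normoxic 4 and 204 without normoxic 7, and to 0 (193 at an unadjusted p under 0.05, smallest adjusted p = 0.170) without the 5 tumours of fewest counts, which leaves 2 hypoxic MC38 tumours; there the median of all genes was -1.03 and the median SE 0.67, against 0.55. With each tumour centred on its own median gene, which adds 1.12 to every MC38 difference, 190 genes passed, 75 of them higher and 115 lower. All of the 12 largest falls and the 4 rises passed on that scale too. With the estimated counts scaled on the positive-control probes 214 genes passed, all of them lower.

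Of 24 measured genes named in advance, 10 fell in MC38 and 14 did not pass. Besides Arg1 and Cd163, the falls were Mrc1 (-3.15 ± 0.79), the mannose receptor of macrophages, Ifng (-2.53 ± 0.63; 12.1 ± 8.50 against 68.7 ± 32.0), the interferon gamma gene, Cd4 (-2.24 ± 0.63), the helper T cell co-receptor, and Ctla4 (-2.15 ± 0.66), a target of the treatment. Il10 (-1.72 ± 0.54), an anti-inflammatory cytokine, Itgam (-1.72 ± 0.54), an integrin of myeloid cells, Tigit (-1.41 ± 0.52), a checkpoint receptor, and Vegfa (-1.23 ± 0.41), the hypoxia-inducible vascular growth factor, fell as well. All 4 hypoxic tumours lay below the normoxic mean for each of the 10. Values that did not pass were Cd8a at -1.65 ± 0.70 (adjusted p = 0.0585), Pdcd1 at -1.56 (0.0563), Nos2 at -1.15 (0.0611), S100a8 at -1.39, Foxp3 at -1.34 (0.107), Havcr2 at -1.0, Gzmb at -0.89 (0.204), Cd274 at -0.80 (0.214), Hif1a at -0.74 (0.141), Lag3 at -0.37, Prf1 at -0.13, Cxcl9 at -0.03, Tgfb1 at 0.41 and Cxcl10 at 1.12 (0.120). Some of these calls changed with single tumours. Ctla4 did not pass without normoxic 4, normoxic 7 or hypoxic 25 (-2.71 to -1.86 over the 16 fits without 1 tumour), nor Vegfa without normoxic 4, normoxic 7, hypoxic 14 or hypoxic 25 (-1.46 to -0.91). Il10 did not pass without normoxic 7, normoxic 21 or hypoxic 25 (-2.15 to -1.43), nor Itgam without normoxic 4, hypoxic 12 or hypoxic 25 (-2.04 to -1.24). Tigit did not pass without normoxic 4, normoxic 7, normoxic 21, hypoxic 12 or hypoxic 25 (-1.86 to -1.20). Cd8a passed without MC38 hypoxic 17 or E0771 normoxic 4 (-2.04 to -1.31), and Foxp3 (-1.73 to -0.74) and Cxcl10 (0.39 to 1.62) passed without MC38 normoxic 10. Nos2 passed without MC38 normoxic 10 or hypoxic 17 (-1.37 to -0.77), and Pdcd1 without either of them or without E0771 normoxic 4 or 17 or E0771 hypoxic 12 or 22 (-1.81 to -1.40). Relative to the median gene, Arg1, Cd163, Mrc1, Ifng and Cd4 still passed, and Ctla4 (-1.03, adjusted p = 0.0578), Il10 (-0.60), Itgam (-0.60), Tigit (-0.29) and Vegfa (-0.11) did not. On that scale Cxcl10 (2.24, adjusted p = 0.0277) and Tgfb1 (1.53, adjusted p = 0.0443) were higher in the hypoxic tumours.

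**Figure D2:**
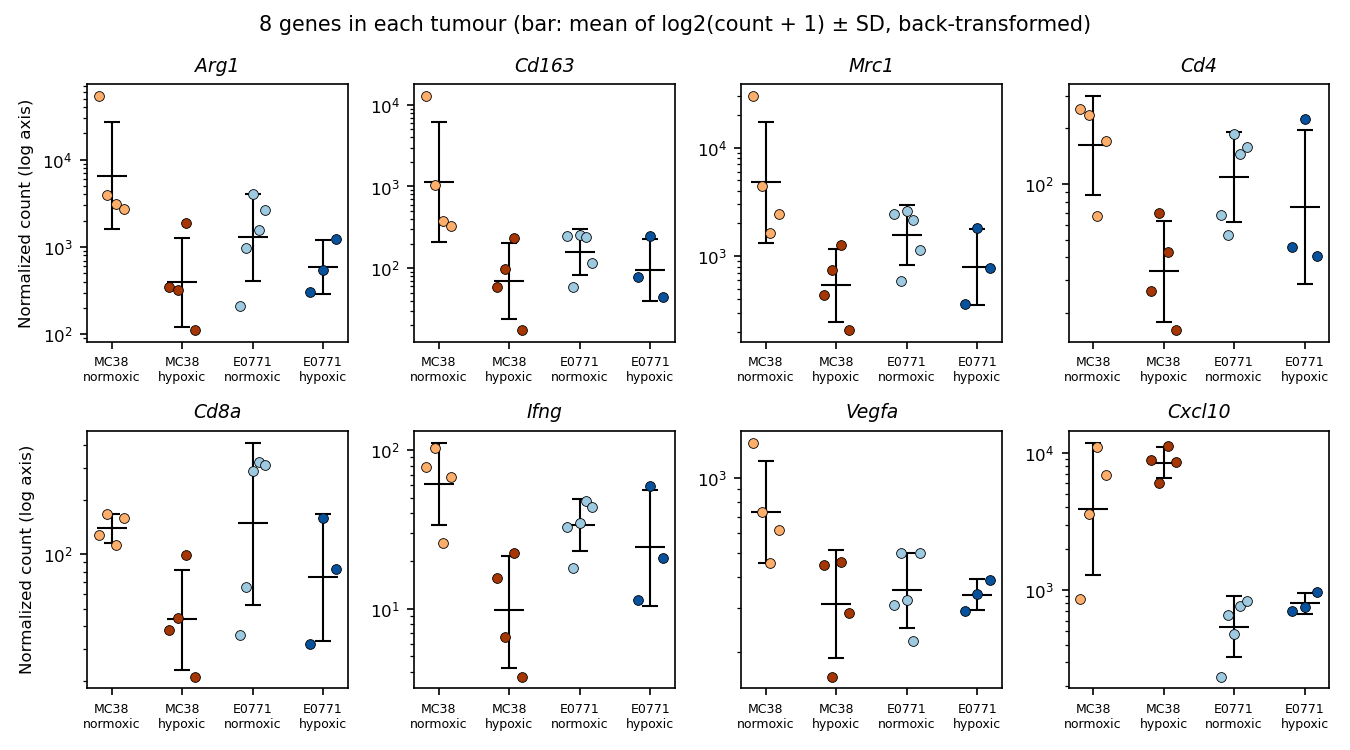
Normalized counts (vertical log axis) of 8 genes in each tumour by line and hypoxia status (horizontal axis), 1 point per tumour, with bars for the mean of log2(count + 1) ± SD turned back to counts (MC38 n = 4 and 4; E0771 n = 5 normoxic and 3 hypoxic). In MC38, Arg1, Cd163, Mrc1, Cd4, Ifng and Vegfa fell (-4.04, -4.00, -3.15, -2.24, -2.53 and -1.23 on the log2 scale), Cd8a (-1.65) and Cxcl10 (1.12) did not pass, and none of the 8 passed in E0771, while centring each tumour on its median gene turns no sign of these 8 in MC38.

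Of 25 gene lists, 22 were lower in hypoxic MC38 tumours by fry, limma's rotation test of gene sets, with adjusted p = 0.00755 to 0.0420. This test asks whether the genes of a set move, on balance, one way and does not compare a set with other genes. None of the 22 was called by camera, which compares a list with the other genes (adjusted p = 0.893 to 0.986, with a correlation between genes estimated from the data). Values given below with an estimated correlation are from this test. As 87.2% of all genes were negative, camera asks whether a list fell more than the panel, not whether it fell. The 22 calls were also lost when tumours were permuted (exact two-sided permutation, adjusted p = 0.0621 to 0.0893, unadjusted p = 0.0286 to 0.0857, n = 4 and 4). With so few tumours 0.0286 is the smallest unadjusted p this permutation can give, so the loss may reflect that limit. For all 22 the 4 hypoxic tumours lay below the normoxic mean. The number of lists called was 13 without normoxic 4 or hypoxic 25, 14 without normoxic 7, normoxic 21 or hypoxic 14, and 13, of which 10 were lower, with median centring. It was 0 without the 5 tumours of fewest counts and 0 with positive-control scaling, with 22 lists at an unadjusted p under 0.05 as deposited.

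Of 13 B cell genes 11 fell in MC38 (11 adjusted over the list alone), with a list median of -2.49 (fry adjusted p = 0.00755; 0.893 with an estimated correlation); examples were the IgE receptor Fcer2a (-3.22) and Ms4a1 (-3.10), which encodes CD20. Of 17 T cell genes 9 fell (9 over the list alone; median -1.70), among them the adhesion receptor Cd2 (-3.17) and the co-stimulatory receptor Cd28 (-2.56), while Tcf7 (-0.56) and Sh2d1a (-0.68) did not pass. In the list of CD8 and cytotoxic effector genes 5 of 16 fell (5 over the list alone; median -1.29), including Tbx21 (-2.66), the Th1 transcription factor, and Cd8b1 (-2.64), the second chain of CD8. Among NK cell genes 9 of 12 fell (10 over the list alone; median -1.66), with Klra3 (-2.86) and Klrb1c (-2.58), both NK receptors, and Klra4 at 0.66 not passing. Among regulatory T cell genes 10 of 12 fell (10 over the list alone; median -2.06), with Ccr4 (-3.02), a homing receptor, and Tnfrsf18 (-2.59), which encodes GITR. Among immune checkpoint genes 12 of 19 fell (14 over the list alone; median -1.48), with Pdcd1lg2 and the inhibitory receptor Btla (-3.08). The calls of the T cell, NK cell, regulatory T cell and checkpoint lists had an adjusted p = 0.893 with an estimated correlation, and that of the CD8 list 0.926. With median centring, the B cell (-1.37), regulatory T cell (-0.94), NK cell (-0.54) and checkpoint (-0.36) lists were still called lower, and the T cell (-0.57) and CD8 (-0.17) lists were not called.

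Of 8 mast cell and eosinophil genes 6 fell in MC38 (7 adjusted over the list alone; median -2.70), including Prg2 and Ccr3, while Il1rl1, the IL-33 receptor, was at 0.92 and did not pass. Of 16 dendritic cell genes 13 fell (13 over the list alone; median -1.97), including Cd209e and Flt3 (-2.90), the receptor needed for dendritic cell development. Of 16 neutrophil genes 11 fell (11 over the list alone; median -1.79), including Cxcr1 and Cxcr2 (-3.21). Of 18 macrophage genes 11 fell (12 over the list alone; median -1.49), including Cd163 and Mrc1. Of 21 immunosuppressive myeloid genes 12 fell (12 over the list alone; median -1.72), including Ccl24 and Chil3, with Cebpb at 0.35 not passing. The first 3 of these lists had an adjusted p = 0.893 with an estimated correlation, and the macrophage and immunosuppressive lists 0.918. After centring on the median gene, the mast cell and eosinophil (-1.58), dendritic cell (-0.85) and neutrophil (-0.66) lists were still called lower, and the macrophage (-0.37) and immunosuppressive myeloid (-0.60) lists were not called.

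Of 10 MHC class II genes 7 fell in MC38 (7 adjusted over the list alone; median -1.82; adjusted p = 0.893 with an estimated correlation), including H2-DMb2 (-2.96), a peptide-loading chaperone, and its modulator H2-Ob (-2.83); centred on the median gene, this list was not called (-0.70, adjusted p = 0.106). The MHC class I list was not called (median 0.01, mean -0.56, fry direction down, adjusted p = 0.145). Of its 15 genes 3 fell (3 over the list alone), including the non-classical genes H2-Q1 (-3.13) and H2-Q10 (-2.76), and the proteasome gene Psmb10 (0.84) and the peptide-loading gene Tapbp (0.71) did not pass. The type I interferon response list was not called either (median 0.27, adjusted p = 0.333). Of its 23 genes 2 rose (0 over the list alone), and Rsad2 (1.24, adjusted p = 0.0675) and Ifi44 (1.17), antiviral effectors, did not pass. Relative to the median gene both lists were called higher in hypoxic tumours (type I interferon 1.39, adjusted p = 0.0267; MHC class I 1.13, adjusted p = 0.0344); over the fits with other scaling or background these adjusted p ranged to 0.610 and 0.504. In the interferon gamma and Th1 list 13 of 22 genes fell (13 over the list alone; median -1.28; adjusted p = 0.918 with an estimated correlation), including Gbp2b (-2.88), an interferon-induced GTPase, and Tbx21, while the chemokines Cxcl11 (1.18) and Cxcl10 did not pass; centred, this list was not called (-0.15).

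Among soluble mediators, 10 of 15 inflammatory cytokine genes fell in MC38 (10 adjusted over the list alone; median -1.78), including Tnfsf14 (-2.99), which encodes LIGHT, and Il17f (-2.82). In the list of myeloid attracting chemokines and growth factors 10 of 15 fell (10 over the list alone; median -1.77), including Cxcl5 (-3.20), which draws neutrophils, and Ccl9 (-3.01), with Cxcl1 (0.69) and Ccl2 (-0.00) not passing. Of 26 complement genes 23 fell and C1qbp rose (24 and 1 over the list alone; median -2.14), with the lectin pathway genes Mbl2 (-3.20) and Masp2 (-3.17) among the falls. Of 29 NF-kB and Toll-like receptor genes 12 fell (12 over the list alone; median -1.05), including Tlr6 (-2.71) and Tlr5 (-2.60). The list of T cell attracting chemokines was not called (median -0.76, adjusted p = 0.246); 3 of its 10 genes fell (1 over the list alone), among them Ccl19 (-3.09) and Cxcl13 (-2.21), which guide lymphocytes. With an estimated correlation the adjusted p was 0.893 for the cytokine and complement lists and the chemokine list of myeloid cells, and 0.986 for the NF-kB list. When tumours were centred on the median gene, complement (-1.02), inflammatory cytokines (-0.66) and myeloid attracting chemokines (-0.65) were still called lower, whereas the NF-kB list (0.07) and the T cell attracting chemokines (0.37) turned sign and were not called.

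In MC38, 5 of 18 fibroblast and matrix genes fell (4 adjusted over the list alone; median -1.14, and -0.02 with the test's direction up when centred on the median gene), including Col3a1 (-2.23), a fibrillar collagen, and Fap (-2.08). Of 18 endothelial genes 6 fell (6 over the list alone; median -0.84, and 0.28 and called higher when centred), including Sele (-2.64), which encodes E-selectin, and Tek (-1.98), the angiopoietin receptor. Of 14 epithelial and tumour cell genes 6 fell (3 over the list alone; median -0.84, and 0.29 when centred), including Cdh1 (-2.60), which encodes E-cadherin, and Hras (-2.57), with Itgb4 (0.84) and Myc (0.82) not passing. Of 19 apoptosis and cell cycle genes 5 fell (3 over the list alone; median -0.28, and 0.84 when centred), including Bcl2 (-1.86) and the death receptor Fas (-1.73), with Trp53 at 0.44 not passing. Of 11 hypoxia and HIF target genes 3 fell and none rose (2 over the list alone; median -0.74, fry adjusted p = 0.0420, and 0.38 when centred). The falls included Nt5e (-1.36, adjusted p = 0.0439), which makes adenosine, and Vegfa; Cxcr4 (-1.34), Plaur (0.56) and Tfrc (0.53) did not pass. Slc2a1, Pgk1, Ldha, Hk2, Ca9, Adm, Bnip3, Egln3, Ndrg1, Angptl4 and Pdk1 of the hypoxia list are not on the panel. Most of the HIF targets chosen were thus not measured, and the list says little about the response to low oxygen. All 5 lists had an adjusted p = 0.893 with an estimated correlation.

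**Figure D3:**
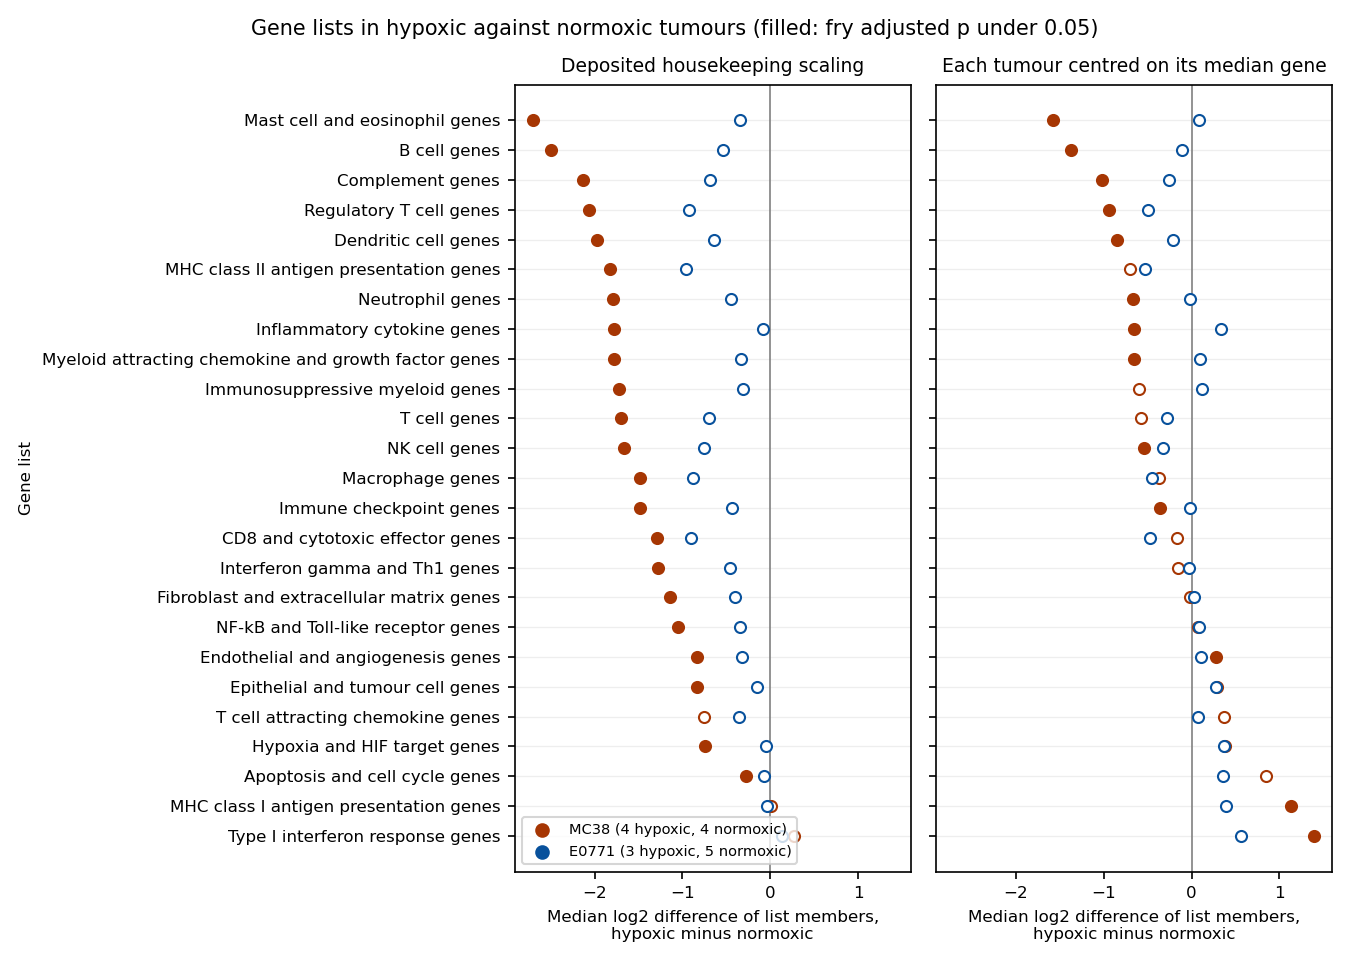
Median log2 difference, hypoxic minus normoxic, of the tested members of each of 25 gene lists (horizontal axis) in MC38 (4 and 4 tumours) and E0771 (3 and 5 tumours), on the deposited scale (left) and with each tumour centred on its median gene (right); filled points had a fry adjusted p under 0.05. On the deposited scale 22 MC38 lists were lower; on the centred scale 10 were lower and MHC class I (1.13), type I interferon (1.39) and endothelial genes (0.28) were higher, and the hypoxia, NF-kB, endothelial, epithelial, T cell attracting chemokine and apoptosis lists turned sign in both lines, as did the immunosuppressive myeloid, mast cell, MHC class I, myeloid attracting chemokine, inflammatory cytokine and fibroblast lists in E0771.

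The same question was asked of E0771, with 3 hypoxic and 5 normoxic tumours, and no gene passed (limma, 0 of 712). The number at an unadjusted p under 0.05 was 45, the smallest adjusted p was 0.620, the median of all genes was -0.36, and 71.3% of genes had negative values. The 10 genes of smallest p all had that adjusted p. Ccl17, a chemokine that draws T cells with CCR4, was at -2.49 ± 0.81 (39.1 ± 19.6 normalized counts in hypoxic and 305 ± 290 in normoxic tumours, SD). The Fc receptor gene Fcgr3 was at -2.32 ± 0.77 (223 ± 214 against 933 ± 501), and Cd34, a marker of vessels and progenitors, at -1.81 ± 0.48 (242 ± 86.4 against 1000 ± 608). Cfp, which encodes properdin, was at -1.74 ± 0.61, Cd55, a complement regulator, at -1.97 ± 0.78, Jaml at -1.62 ± 0.59, the lymph node homing receptor Ccr7 at -1.32 ± 0.51, Igf2r at -1.25 ± 0.39 and osteopontin (Spp1) at -1.13 ± 0.40. Mfge8, which bridges dying cells to phagocytes, was at 0.84 ± 0.32 and was the only positive value among the 10; it was at -0.36 with positive-control scaling. For Cfp and Igf2r all 3 hypoxic tumours lay below every normoxic one.

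None of the 24 genes named in advance passed in E0771. Treg and T cell genes had values of -1.13 (Foxp3), -0.97 (Cd8a), -0.53 (Cd4), -1.05 (Gzmb), -0.45 (Ifng), -0.29 (Prf1), -0.93 (Ctla4), -0.74 (Pdcd1), -0.16 (Lag3), -0.05 (Havcr2) and -0.00 (Tigit). Myeloid and ligand genes had values of -1.13 (Arg1), -0.97 (Mrc1), -0.74 (Cd163), -0.73 (Itgam), -0.17 (Nos2), -0.08 (Il10), -0.25 (Cd274), -0.37 (Cxcl9), 0.45 (S100a8), 0.56 (Cxcl10) and 0.76 (Tgfb1), and Hif1a and Vegfa were at -0.09 and -0.06.

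No list was called in E0771 (fry, 0 of 25; 0 at an unadjusted p under 0.05; smallest adjusted p = 0.699, 0.976 by camera and 0.568 by permutation of tumours). List medians were -0.95 for MHC class II, -0.92 for regulatory T cells, -0.90 for CD8 and cytotoxic genes, -0.88 for macrophages, -0.75 for NK cells, -0.70 for T cells, -0.68 for complement, -0.64 for dendritic cells, -0.53 for B cells and -0.46 for interferon gamma and Th1 genes. The neutrophil and checkpoint lists were both at -0.44. Medians of -0.40 for fibroblast, -0.35 for T cell attracting chemokine, -0.35 for mast cell and eosinophil, -0.34 for NF-kB, -0.33 for myeloid attracting chemokine, -0.32 for endothelial, -0.31 for immunosuppressive myeloid, -0.15 for epithelial, -0.09 for inflammatory cytokine, -0.07 for apoptosis, -0.05 for hypoxia and -0.04 for MHC class I genes turned positive when centred on the median gene. The type I interferon list was at 0.14 and at -1.03 with positive-control scaling. The MHC class I list had a mean of 0.07 and the hypoxia list one of -0.04, and fry's direction was up for both. Adjusted over the list alone, 1 gene passed in all 25 lists, Cd34 in the endothelial list.

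The 0 calls in E0771 depended on a few settings. Without E0771 normoxic 17, 1 gene passed, with adjusted p = 0.00950 (Cd34, at -2.25 to -1.52 over the fits without 1 tumour). With array quality weights 43 genes passed, and with positive-control scaling 75, all lower; the smallest adjusted p over all other settings ran from 0.150 to 0.997. Hypoxic 12 and 22 had the fewest estimated counts (192035 and 180274) and the highest positive-probe sums (57450 and 52801), unlike hypoxic 55 (629162 and 41792). Positive-control scaling therefore lowers all genes of these 2 tumours, housekeeping genes included. As RNA input is unknown, the 75 falls cannot be told apart from a lower input. With median centring 0 passed (76 at an unadjusted p under 0.05) and the median of all genes was 0.07.

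Whether the effect of hypoxia status differed between the lines was tested as an interaction. No gene passed (limma, 0 of 712; 133 at an unadjusted p under 0.05; smallest adjusted p = 0.205). The genes of smallest p included Nod2, a sensor of bacterial cell walls (E0771 minus MC38 effect 2.40 ± 0.67), Card9, an adaptor of fungal recognition (3.40 ± 1.0), the heat shock gene Hspb2 (3.20 ± 0.93) and the protease receptor gene F2rl1 (3.02 ± 0.93); each fell in MC38 (-1.99, -3.38, -2.40 and -2.94) and was at 0.41, 0.02, 0.80 and 0.08 in E0771. Card9 was near the filter level in both E0771 groups (25.7 and 26.0 against 24.0), so it could hardly have fallen there and its difference between the lines says little. No list passed (0 of 25; 3 at an unadjusted p under 0.05, smallest adjusted p = 0.244), although the largest list difference, mast cell and eosinophil genes, was 2.24. Some members of that list also had little room to fall in E0771. Il5ra (14.2 in hypoxic and 22.8 in normoxic tumours) and normoxic Ms4a2 (18.1) lay under the filter level, while Ccr3 (55.9 and 95.7) and Il1rl1 (115 and 135) lay above it. So the falls called in MC38 are not shown to be absent from E0771. Without MC38 normoxic 10, 132 genes, all of them higher in E0771, and 8 lists passed, and with array quality weights 119 genes and 1 list. With median centring, positive-control scaling, background subtraction and precision weights 0 genes passed (93, 12, 52 and 71 at an unadjusted p under 0.05). Across the 712 genes the effects in the lines had r = 0.466 (exact permutation over 3920 relabellings of hypoxia status within line, p = 0.132) and rho = 0.475 (p = 0.139). Genes are not independent replicates, and 76.8% of them had the same sign in both lines. Without E0771 hypoxic 22 the correlation was 0.596 (permutation p = 0.0395, over its alternatives 0.0367 to 0.454). Of the 342 genes that fell in MC38, 289 had negative values in E0771, where 71.3% of all 712 genes were negative. The count was not tested against that share.

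Over the mean of both lines, Ccl24 fell by 3.48 ± 0.80 and Ccl17 by 2.96 ± 0.56, and Chil3 (-2.89 ± 0.75), Arg1 (-2.59 ± 0.73), Fcgr3 (-2.54 ± 0.53) and Ccl19 (-2.42 ± 0.49) fell as well. Hsd11b1, which activates glucocorticoids, fell by 2.41 ± 0.56, Cd163 by 2.37 ± 0.71, Ccl9 by 2.32 ± 0.49, and the eosinophil chemokine gene Ccl11 by 2.26 ± 0.54; Cd209e (-2.71) and Ccr3 (-2.31) completed the 12 largest falls. Genes that rose included Myc (0.96 ± 0.33), Dusp4 (0.82 ± 0.28), a phosphatase of MAP kinases, Ifi35 (0.78 ± 0.26) and Nfkb2 (0.70 ± 0.27), a subunit of NF-kB. For Myc, Dusp4 and Ifi35, all 4 hypoxic MC38 and all 3 hypoxic E0771 tumours lay above the normoxic mean of their line. In total 300 genes passed (limma; 295 lower; smallest adjusted p = 0.0184), the median of all genes was -0.89, and 85.0% had negative values. The mean includes the MC38 effect, so it is not independent of it, and 269 of the 300 genes also passed in MC38. Among the genes named in advance Mrc1 (-2.06), Ctla4 (-1.54), Ifng (-1.49), Cd4 (-1.38), Cd8a (-1.31, adjusted p = 0.0452), Foxp3 (-1.23, adjusted p = 0.0499) and Itgam (-1.22) fell beside Arg1 and Cd163, and 15 did not pass, including Pdcd1 (-1.15, adjusted p = 0.0548), Gzmb (-0.97, adjusted p = 0.0679), Vegfa (-0.64, adjusted p = 0.0804), Cd274 (-0.53) and Cxcl10 (0.84).

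The number of calls changed with single tumours. Without E0771 hypoxic 12, 0 genes passed (295 at an unadjusted p under 0.05, smallest adjusted p = 0.0662) and 0 lists, with the median of all genes at -0.75 against -0.89. The number of genes was 93 without MC38 hypoxic 25, 109 without MC38 normoxic 4, 131 without E0771 hypoxic 55, 149 without MC38 normoxic 7, 177 without E0771 normoxic 38 and 198 without MC38 normoxic 21. Without the 3 E0771 tumours of fewest counts, which leaves 1 hypoxic E0771 tumour, 0 passed (278 at an unadjusted p under 0.05), with that median at -0.85. Relative to the median gene, 145 passed, 80 of them higher and 65 lower, and with positive-control scaling 405, all lower. Of the 12 largest falls and Mrc1, all lost their call without E0771 hypoxic 12, and Cd163 also without MC38 hypoxic 25 or E0771 hypoxic 55 (-2.71 to -1.79 over the 16 fits without 1 tumour). Ifng (-1.80 to -1.23) and Itgam (-1.38 to -0.98) lost it without MC38 normoxic 4, MC38 hypoxic 25, E0771 hypoxic 12 or E0771 hypoxic 55. Without those 4 or MC38 normoxic 7 the calls of Ctla4 (-1.86 to -1.24) and Dusp4 (0.67 to 0.94) were lost, and without any of these 5 or E0771 normoxic 38 those of Cd4 (-1.78 to -1.17) and Ifi35 (0.61 to 0.94). The same 6 and MC38 hypoxic 12 changed the call of Myc (0.78 to 1.11). Cd8a kept its call only without MC38 normoxic 10, MC38 hypoxic 17 or E0771 normoxic 4, normoxic 17 or hypoxic 22 (-1.58 to -1.01), and Foxp3 only without MC38 normoxic 10 or the same E0771 tumours (-1.50 to -0.94). Nfkb2 kept it only without MC38 normoxic 10, MC38 hypoxic 17 or E0771 hypoxic 55 or normoxic 65 (0.57 to 0.92). Pdcd1 passed without MC38 normoxic 10, MC38 hypoxic 17 or E0771 normoxic 4, normoxic 17 or hypoxic 22 (-1.45 to -0.80), and Gzmb without E0771 normoxic 4 or 17 (-1.22 to -0.81). Il10, at -0.90, passed without MC38 normoxic 10 or E0771 hypoxic 22 (-1.11 to -0.75), and Vegfa (-0.76 to -0.48), Cxcl10 (0.48 to 1.09) and Tigit (-0.93 to -0.57) passed without MC38 normoxic 10.

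Over both lines 20 lists were lower (fry adjusted p = 0.0158 to 0.0456; adjusted p = 0.687 to 0.992 with an estimated correlation; 0.0300 to 0.0478 by permutation of hypoxia status within line). Of the genes in lymphocyte lists, 11 of 17 T cell (13 adjusted over the list alone; median -1.44), 10 of 13 B cell (11; -1.38), 9 of 12 regulatory T cell (11; -1.37), 9 of 12 NK cell (9; -1.24), 6 of 16 CD8 (6; -1.11) and 9 of 19 checkpoint genes (10; -1.09) fell, with Cd2 (-2.24) and Ms4a1 (-2.13) as examples. Of myeloid and antigen presentation lists, 4 of 8 mast cell and eosinophil (4; -1.64), 7 of 10 MHC class II (9; -1.43), 12 of 16 dendritic cell (15; -1.31), 9 of 16 neutrophil (9; -1.26), 12 of 18 macrophage (14; -1.20) and 9 of 21 immunosuppressive genes (9; -0.90) fell, H2-DMb2 (-2.09) among them. Of mediator lists, 19 of 26 complement (24, with 1 higher; -1.40), 9 of 15 myeloid attracting chemokine (9; -1.10), 12 of 22 interferon gamma and Th1 (12; -1.05), 6 of 15 inflammatory cytokine (6; -0.95) and 12 of 29 NF-kB genes (14; -0.54, and 0.23 when centred) fell, and Nfkb2 rose. The endothelial (5 of 18; -0.51, and 0.26 when centred), fibroblast (5 of 18; -0.72, and 0.05 when centred) and apoptosis lists (2 of 19; -0.22, and 0.55 when centred) were also called. Not called were the epithelial (-0.44, adjusted p = 0.0773, and 0.33 when centred), hypoxia (-0.49, 0.176, and 0.29), T cell attracting chemokine (-0.43, 0.176, and 0.35) and MHC class I lists (-0.08, 0.462, and 0.69). The type I interferon list, at 0.14 (0.444) and at -0.40 with positive-control scaling, was not called either. With median centring no list was called (smallest adjusted p = 0.0520). Without MC38 normoxic 4, 11 lists were called, and without MC38 hypoxic 25 or E0771 hypoxic 55, 13.

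The last comparison set the lines against each other at equal weight of hypoxic and normoxic tumours, with 8 tumours each. MC38 and E0771 tumours are not shown in the labels to have been run together, so line and batch cannot be told apart. Il1rl1, the IL-33 receptor, was lower in E0771 (-4.68 ± 0.46, adjusted p = 2.37e-06), with mean normalized counts of 115 and 135 in hypoxic and normoxic E0771 and 3606 and 2493 in MC38. Mesothelin (Msln; -4.35 ± 0.44; 13.0 and 14.4 against 478 and 200) and osteopontin (Spp1; -3.46 ± 0.28, adjusted p = 4.03e-07; 976 and 1975 against 14947 and 14788) were lower too. The E0771 means of Msln and of Ido1 (12.5 and 16.9) lay under the filter level of 24.0, where background adds most to a value. The chemokines Cxcl10 (-3.12 ± 0.42) and Cxcl1 (-3.06 ± 0.43), the lymphatic growth factor Vegfc (-2.98 ± 0.34), the tryptophan-degrading enzyme Ido1 (-2.86 ± 0.32), the prostaglandin synthase Ptgs2 (-2.77 ± 0.57), Cd34 (-2.69 ± 0.34), Lcn2 (-2.66 ± 0.26), Lif (-2.66 ± 0.31) and Ifna1 (-2.41 ± 0.67) completed the 12 largest falls. Higher in E0771 were Nt5e (2.32 ± 0.38), the laminin receptor chain Itga6 (2.31 ± 0.28), the basement membrane collagen Col4a1 (2.07 ± 0.30), F2rl1 (2.0 ± 0.47), Cd9 (1.88 ± 0.28), the fibronectin receptor chain Itga5 (1.77 ± 0.26), Clu (1.77 ± 0.29), St6gal1 (1.73 ± 0.38), the endothelial co-receptor Eng (1.72 ± 0.33), the MHC class II gene H2-Ab1 (1.68 ± 0.51), Adgre5 (1.61 ± 0.35) and Hspb2 (1.61 ± 0.46). For some of these genes the lines were further apart in one hypoxia class: the means in E0771 and MC38 were 173 and 16.2 in hypoxic and 86.2 and 96.3 in normoxic tumours for Hspb2, 229 and 23.7 against 224 and 195 for F2rl1, 230 and 30.7 against 213 and 194 for St6gal1, and 59.9 and 75.0 against 77.1 and 961 for Ifna1. Called in every fit without 1 tumour were 10 of these 12 rises and 11 of these 12 falls. H2-Ab1 kept its call only without MC38 normoxic 4, MC38 hypoxic 14, MC38 hypoxic 17 or E0771 normoxic 4 or 17 (1.46 to 1.99). Hspb2 lost it without MC38 hypoxic 12, MC38 hypoxic 25 or E0771 hypoxic 22 (1.29 to 1.79), and Ifna1 without MC38 normoxic 7, MC38 hypoxic 17, MC38 normoxic 21, E0771 hypoxic 12 or E0771 hypoxic 55 (-2.97 to -2.09). In all 97 genes passed, 34 higher and 63 lower in E0771 (limma; median of all genes -0.12). Relative to the median gene 131 passed (49 higher, 82 lower), and with positive-control scaling, where the median was -0.94, 200 passed (2 higher, 198 lower). Of the 12 rises 2 passed on that last scale, and of the 12 falls all.

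Of the 25 lists 1 differed between the lines, the type I interferon response, which was lower in E0771 (median -0.86, fry adjusted p = 0.0312). In this list 11 of 23 genes were lower, 13 adjusted over the list alone, with Ifitm1 (-2.14) and Rsad2 (-1.92) as examples. Its adjusted p was 0.920 by camera with an estimated correlation. By permutation of all tumours between the lines, without regard to hypoxia status, it was 0.0350. With median centring its adjusted p was 0.0742 (0.0237 to 0.0742 over the scaling and background alternatives). Medians of -0.88 (myeloid attracting chemokines, 4 of 15 lower, adjusted p = 0.0600), -0.94 (inflammatory cytokines, 4 of 15 lower), -0.77 (T cell attracting chemokines), -0.70 (mast cell and eosinophil), -0.60 (B cell), -0.49 (endothelial), -0.48 (immunosuppressive myeloid), -0.43 (neutrophil), -0.43 (NK cell), -0.26 (apoptosis), -0.20 (complement) and -0.06 (MHC class I) did not pass, nor did 0.70 (MHC class II, 1 of 10 higher, 4 over the list alone; -0.12 with positive-control scaling), 0.45 (T cell), 0.21 (macrophage) and 0.14 (regulatory T cell), the last 3 at -0.38, -0.63 and -0.65 with positive-control scaling. Median, mean and test differed in sign for the hypoxia (0.08, -0.45, down), CD8 (0.02, -0.11, down), interferon gamma (0.16, -0.21, down), dendritic cell (0.16, -0.02, up), checkpoint (-0.00, 0.04, down), NF-kB (-0.09, 0.01, up), fibroblast (-0.00, -0.03, up) and epithelial lists (-0.29, -0.04, up), none of which passed. With positive-control scaling the hypoxia (-0.75), CD8 (-0.82), interferon gamma (-0.66) and dendritic cell medians (-0.67) were negative, and with median centring the checkpoint (0.02) and fibroblast medians (0.02) positive. Lists called numbered 9 when centred and 0 without MC38 normoxic 7, MC38 normoxic 21, MC38 hypoxic 12, MC38 hypoxic 17, E0771 hypoxic 12 or E0771 normoxic 38. They numbered 2 without MC38 hypoxic 25, 4 without MC38 normoxic 10 and 5 without E0771 hypoxic 22.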

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

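All tests of explanations in this part and the counts of other splits were read with the results already seen. Within groups of 4 or 5 tumours, 9 of 324 sets of values had 1 tumour far from the rest, where chance alone gives about 1 in 20, or 16.2, so the number itself is not above chance. 4 of the 9 fell on MC38 normoxic 10. Its mean log2 level of T cell genes was 6.04 (7.24 to 7.46 in the other normoxic MC38 tumours) and of interferon gamma and Th1 genes 7.53 (8.29 to 8.41), and its normalized counts were 199 for Havcr2, a checkpoint receptor (328 to 361), and 29.5 for Pdgfrb, a pericyte receptor (107 to 134). MC38 normoxic 4 was high in Arg1 (53233, others 2734 to 3969) and Hif1a (8261, others 2226 to 2701). MC38 hypoxic 17 was high in Ccl24 (28.3, others 9.92 to 11.4) and Pdcd1lg2 (62.4, others 13.2 to 14.9), and E0771 normoxic 17 was low in Ccr7 (89.9, others 236 to 248).

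The first pattern is the broad fall of immune genes in hypoxic MC38 tumours, for which chance could not be excluded, since 2 of the 35 splits of the 8 tumours called as many genes (real 346, highest other 371). These tests argue against housekeeping scaling as the whole cause of the strongest falls and against 1 tumour. Lower both as deposited and relative to the median gene were 115 genes, and at least 171 genes passed without any single tumour. With background subtracted 300 genes passed. The scaled negative probes averaged 2.69 to 6.68 in normoxic and 2.86 to 6.82 in hypoxic MC38 tumours. Background of that kind was thus alike in both groups, and subtracting it could change little. Signal that these probes do not capture was not tested. For the breadth of the fall the scaling cannot be told apart from a lower immune content. Scaled on the positive-control probes the median was still -1.16, against -1.27 as deposited, and the genes that passed were all lower. No list was called on that scale, but with a median so little changed this loss does not speak for the housekeeping scaling. The question stays open because that scale does not correct for RNA input, which is unknown. A smaller share of leukocytes may contribute, as the 7 leukocyte lists had a mean difference of -1.96 and no list was detected to depart from the others (smallest adjusted p = 0.259, largest departure 0.41); centred on the mean of these lists 261 MC38 genes passed, 240 of them higher, and centred on Ptprc, the leukocyte gene CD45, 0 passed, as the median of all genes went from -1.27 to 0.51 and the spread of that 1 gene (-1.78 ± 0.75) entered every difference. Whether it extends to the stromal lists stays open, because median centring adds the same 1.12 to every gene and so decides nothing (endothelial 0.28).

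The second pattern is the set of genes called over the mean of both lines. Chance as the source of the number was excluded only to the share that 100 drawn splits allow, 0.01, as 1 of 100, the real one, gave as many genes (real 300, highest other 219), and for the comparison of the lines likewise (1 of 100; real 97, highest other 68). Background at the level of the negative probes does not account for these calls, as 344 genes passed with it subtracted. A dependence on 1 tumour stays open: 0 genes passed without E0771 hypoxic 12, but the median of all genes was -0.75 against -0.89 and the median SE 0.42 against 0.40. The smaller difference is what this tumour had added, and fewer tumours also lower the precision. How much each of these moved genes past the threshold was not tested. In E0771 alone (56 of 56 splits; real 0, highest other 134, for normoxic 38, 65 and 71 against the rest) and for the interaction (100 of 100; real 0, highest other 242) every split calls at least 0 genes, so the splits cannot bear on chance, but splits with so many genes point to a structure of the samples, which was not tested further.

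The third pattern is that MC38 normoxic 10 and hypoxic 17 have nearly the same profile (r = 0.989 across genes, the highest of the 28 MC38 pairs). Exchanging their labels gave 371 genes against the real 346, a difference that cannot be told apart from their lying between the groups. An exchange of labels may be a candidate explanation, but a pair of tumours of intermediate state predicts the same, and no PET value was analysed here to separate these. The closest E0771 pair, normoxic 17 and hypoxic 55 (r = 0.983), also had opposite status.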

How the results depend on the processing

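Background subtraction, precision weights, the filter at 20, both fits without low-count tumours, positive-control scaling and the mouse number as a block were tests chosen only after the result was seen. Over 37 settings, 20240 of 21767 compared values kept their call, or their lack of one, or, for counts, moved by at most 1.5 times. Many of these values were not called in the main fit, as no gene or list passed in E0771 or for the interaction. The share therefore does not describe how stable the calls were. Counted among the settings is re-centring on housekeeping genes. It could move no number of calls, as their geometric mean was already the same in every tumour. Where a value below moved, the cause was not tested unless fewer tumours entered. With median centring MC38 had 190 genes and 13 lists, both lines 145 genes and 0 lists, and E0771 against MC38 9 lists. In MC38 the hypoxia (0.38), NF-kB (0.073), endothelial (0.28), epithelial (0.29) and apoptosis (0.84) medians reversed, as did the test of the fibroblast list (-0.021), and over both lines the NF-kB (0.23), endothelial (0.26), fibroblast (0.054) and apoptosis (0.55) medians. Array quality weights gave 43 genes in E0771, 498 over both lines, 119 genes and 1 list for the interaction, and 332 genes and 11 lists between lines. Positive-control scaling, which does not correct for RNA input, gave 75 genes in E0771, 214 genes and 0 lists in MC38, and 200 genes and 8 lists between lines. Precision weights gave 167 genes over both lines. A filter at 50, a threshold of 0.10 and background subtraction each gave 2 lists between lines, and the correlation of effects was 0.569 with that filter and 0.631 with background subtracted. Without the 3 low-count E0771 tumours 0 genes and 0 lists passed over both lines and 60 genes and 0 lists between lines. Without all 5, 0 genes and 0 lists passed in MC38 and over both lines, and 33 genes and 0 lists between lines; both of these fits leave 1 hypoxic E0771 tumour, assumed to vary like the others. Camera with an estimated correlation called 0 lists in MC38, over both lines and between lines, and permutation of tumours 0 in MC38.

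Without 1 tumour, genes called ranged from 0 to 1 in E0771, 171 to 420 in MC38, 0 to 402 over both lines, 0 to 132 for the interaction and 72 to 140 between lines. Lists ranged from 13 to 22 in MC38, 0 to 21 over both lines, 0 to 8 for the interaction and 0 to 5 between lines, and the correlation from 0.257 to 0.596. No paired analysis was possible because the hypoxic and normoxic tumours of a line share no mouse number. The lines share 3 numbers (4, 12 and 17), but the labels do not say that these mark the same mouse. Same-numbered tumours did not deviate from their group means together (correlations across genes of -0.147, -0.307 and -0.444), and none correlated best with its own number. With the number as a random replicate block (correlation -0.787), 69 genes and 0 lists passed between lines; as a fixed effect it leaves 0 residual degrees of freedom. Depth limits the genes near background in E0771 hypoxic 12 and 22 and normoxic 65, whose scaled negative probes averaged 15.6 to 24.6.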

Other observations

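The values in this part and the choice of its genes came after the results were seen, and no further tests were made. In hypoxic MC38 tumours Il13, a cytokine that drives mucus and alternative macrophage activation, fell by 3.23 ± 0.66 (17.6 ± 11.5 normalized counts in hypoxic and 189 ± 106 in normoxic tumours, SD, n = 4 and 4; limma adjusted p = 0.00732). The eosinophil chemokine Ccl11 fell by 3.02 ± 0.75 (241 ± 175 against 2167 ± 1418; adjusted p = 0.00812) and the shared receptor chain Il4ra was at -2.04 ± 0.59 (346 ± 162 against 2074 ± 2445; adjusted p = 0.0132). All 4 hypoxic tumours lay below the normoxic mean for each of these, and relative to the median gene the values were -2.11, -1.90 and -0.92. In E0771 they were -0.22, -1.49 and -0.31 and did not pass, and the difference between the lines did not pass either (adjusted p = 0.205, 0.436 and 0.287).

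In the same comparison Ifna1, Ifna2, Ifna4 and Ifnl2, which encode type I and type III interferons, fell (-3.60 ± 0.94, -3.12 ± 0.81, -2.10 ± 0.64 and -3.29 ± 0.71), as did Ifnb1 (-1.48 ± 0.59; adjusted p = 0.0447). The hypoxic means of Ifna2 (9.77 ± 8.84), Il13 and Ifnl2 (18.2 ± 10.7) lay under the filter level of 24.0, above the 2.86 to 6.82 that the scaled negative probes averaged in these tumours. Relative to the median gene the 5 values were -2.48, -2.0, -0.98, -2.17 and -0.36. The receptor genes Ifnar1 (-1.13 ± 0.42) and Ifnar2 (-1.14 ± 0.39) fell on the deposited scale and were at -0.01 and -0.02 relative to the median gene, and Sting1, an adaptor of DNA sensing, fell by 0.99 ± 0.39 but was at 0.13 on that scale. The type I interferon response list was not called in this comparison (median 0.27, adjusted p = 0.333), and no test compared it with these genes. Genes of other kinds fell from similar levels, for example Fcer2a (9.3 ± 7.7 in hypoxic and 97.9 ± 64.3 in normoxic tumours) and Hras (11.4 ± 5.4 against 80.3 ± 49.3). Falls of low-level genes were thus not particular to interferon genes.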
